A study of Rattus norvegicus with 29 samples.

How the data were processed

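Messenger RNA levels were measured by sequencing in 29 libraries of primary rat renal proximal tubule epithelial cells. Treatment and time were taken from the sample labels: control, acetaminophen, gentamicin, TCDD or trichloroethylene, each at 6 h and 24 h. Each of the 10 groups had 3 libraries, except control at 6 h with 2. Per the labels' protocols, RNA was extracted with TRIzol and treated to remove DNA, and libraries followed standard Illumina protocols.

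Per the submitters' processing notes, the authors used kallisto 0.43, which assigns reads to transcripts by pseudoalignment. The deposited tables hold, per the file headers, an estimated count and a TPM value for each of 28420 transcripts, with the transcript's length and effective length. The estimated counts are the authors' expected counts, which need not be whole: 20.1% of the values were not. The deposited TPM values are the authors' scaling of those counts to transcript length and library total. The transcript set, its release, the strand setting and any read trimming are not given in the sources used here. Reads shared between transcripts of 1 gene or of near-identical genes were divided by the authors' tool, so a change may reflect a shift between such transcripts.

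The identifiers could not be turned into gene names. The reference table used here gave an Ensembl identifier for 0 genes, and the files do not pair identifiers with names. Counts were therefore analysed per transcript. The 39 gene lists fixed before the data were examined, the tests planned on them and the genes planned by name were not used here.

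Estimated counts were rounded to whole numbers. Transcripts with low counts were removed with filterByExpr at its minimum count of 10, which left 15990 transcripts and 99.95% of all counts; 5151 of the transcripts left out had no count in any library. The libraries were scaled with TMM factors. With edgeR 4.0.16 in R 4.3.3, 1 quasi-likelihood model with robust dispersion was fitted with a coefficient for each group, leaving 19 residual degrees of freedom, and each comparison was a contrast with an F test. A transcript was called at a Benjamini-Hochberg adjusted p under 0.05. The SE of a log2 change is its size divided by the square root of F. Each compound was compared with the control of its own time, the 2 times were compared by an interaction contrast and in control alone, and compounds were compared in pairs. The design, the tests, the calling threshold and most alternatives were fixed before the data were examined.

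A log2 change was taken from the fit, except where a group had no count in any library. There the group was set at 3 counts in each library, and the resulting lower bound was used in medians and in counts of changes over 2-fold or 4-fold. Mean and SD of TPM are over the libraries of a group. The rule fixed for named genes needs gene names, so it named none. The 4 identifiers printed, 2 that rose and 2 that fell, were chosen after the values were seen. They have the smallest p over the 8 compound comparisons among called transcripts with at least 3 counts in every library of both groups. An earlier choice by size of change had picked transcripts without counts in a group and was dropped.

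Library totals ran from 8243698 to 11446612 estimated counts. No replicates were duplicates: a chi-square test of the counts of each pair of replicates gave between 2.98 and 28.3 per degree of freedom. The median SE of a log2 change was 0.174 against control at 6 h and between 0.155 and 0.161 at 24 h. The steps were tested on simulated counts drawn from the real means, library sizes and dispersions, with 200 of 14946 transcripts changed and 8 draws. For acetaminophen against control at 6 h, 35% of 1.5-fold, 66.7% of 2-fold and 85.7% of 4-fold changes were recovered, with 4.8% of calls false. For acetaminophen at 24 h the shares were 42.3%, 68.5% and 86.5%, with 3.6% false. Simulated unchanged groups against simulated controls, drawn from the real control means, gave the overlap, correlation and covariance that shared controls produce without any effect.

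The alternatives were DESeq2 1.42.0 with its default fit, median-of-ratios factors, no low-count filter, a filter at 10 CPM and a block for the replicate number. Others were only the compared groups in the fit, no robust dispersion, limma 3.58.1 on log2(TPM + 1), and leaving out each library in turn. Further alternatives were chosen after the data were seen: the effective length as an offset, the fragment length of each library as a covariate, and total counts in place of TMM factors. Fragment length was measured as the bases between transcript length and effective length over transcripts of at least 1000 bases. The labels give no sequencing batch or date.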

Results

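RNA was sequenced from primary rat renal proximal tubule epithelial cells, the cells that line the first segment of the nephron and reabsorb most of the filtered solutes. Cultures were left as controls or exposed to 1 of 4 compounds for 6 h or 24 h. The compounds were acetaminophen, an analgesic; gentamicin, an aminoglycoside antibiotic; TCDD, a dioxin that binds the aryl hydrocarbon receptor; and trichloroethylene, an industrial solvent. The 29 libraries fall into 10 groups of 3 libraries each, except the control at 6 h, which has 2 (replicates 2 and 3). Doses and vehicles are not given in the sources used here. The libraries held between 8243698 and 11446612 estimated counts over 28420 transcripts, of which 15990 were tested. The files give transcript identifiers and do not pair them with gene names, so the responses are described by groups of transcripts and by 4 transcripts named by identifier. Nothing in the labels says that the replicates came from separate animals or cultures, so the p-values measure only the spread between these libraries.

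Across the 15990 tested transcripts, the libraries lay apart by compound and by time. The first component of log2 CPM held 22.2% of the variance and placed the acetaminophen libraries of both times away from all others. The second held 20.7% and separated TCDD and gentamicin at 24 h from the remaining libraries. The third held 16.2% and placed gentamicin and TCDD at 24 h at opposite ends. The TCDD and trichloroethylene libraries at 6 h lay with the controls on all 3 components.

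**Figure D1:**
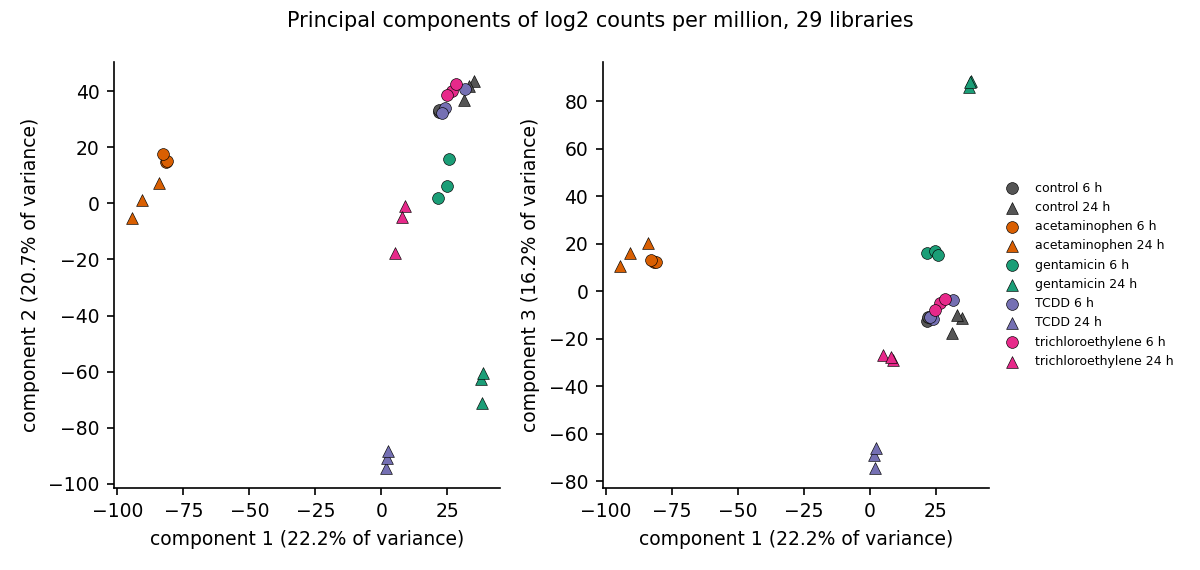
Principal components of log2 CPM in the 29 libraries (each point is 1 library; circles 6 h, triangles 24 h; colour gives the treatment); axes give component scores with the percentage of variance. The acetaminophen libraries lie to the left on component 1 (22.2% of variance), and gentamicin and TCDD at 24 h lie at opposite ends of component 3 (16.2%).

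The early response to acetaminophen was asked by comparing its 6 h libraries with the 2 controls of that time. Of the tested transcripts, 7799 changed: 3876 rose and 3923 fell. The median log2 change was 0.89 among those that rose and -0.78 among those that fell, and 3125 changed by more than 2-fold. In 20 cases a transcript without a count in either control reached at least 10 counts in every treated library, and 4 transcripts showed the opposite. The transcript ENSRNOT00000067423 fell from 49.3 ± 0.907 TPM in controls (SD, n = 2) to 7.93 ± 0.353 TPM (n = 3), a log2 change of -2.59 ± 0.09 (SE; edgeR adjusted p = 8.3e-17). A far more abundant transcript, ENSRNOT00000004956, fell from 1230 ± 49.1 TPM to 850 ± 16.8 TPM, a log2 change of -0.49 ± 0.07 (adjusted p = 2.8e-06). ENSRNOT00000065558 fell from 2.06 ± 0.0239 to 1.23 ± 0.19 TPM (log2 change -0.69 ± 0.15, adjusted p = 4e-04). For all of these, the 3 treated libraries lay below both controls.

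Gentamicin changed fewer transcripts at 6 h, 2113 in all, of which 1333 rose and 780 fell. Rises thus made up 63.1% of the calls. The share was 80.7% when the test was made on log2(TPM + 1), 59.2% with median-of-ratios factors and 57% with DESeq2. Of the called transcripts, 429 changed by more than 2-fold, 337 upward and 92 downward. The transcript ENSRNOT00000001201 rose from 106 ± 0.108 TPM in controls (n = 2) to 216 ± 12.9 TPM (n = 3), with a log2 change of 0.91 ± 0.09 (SE; edgeR adjusted p = 1.2e-07). ENSRNOT00000065558 rose from 2.06 ± 0.0239 to 4.32 ± 0.258 TPM (log2 change 0.95 ± 0.14, adjusted p = 2.2e-05). In each case the 3 treated libraries were above both controls. The size of the count rests on the small control group: it was 881 without control replicate 2 and 980 without replicate 3, where the lone control is assumed to vary like the other groups. With all libraries kept, the gentamicin count under the other settings ran from 1675 on log2(TPM + 1) to 3146 with the fragment length covariate. That covariate was chosen after the data were seen. DESeq2 gave 2582. Directly compared at 6 h, acetaminophen and gentamicin differed in 8711 transcripts.

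At 6 h, no transcript passed the edgeR test for TCDD or for trichloroethylene. At an unadjusted p under 0.05, 1124 transcripts stood out for TCDD and 2070 for trichloroethylene, where chance alone gives about 800. DESeq2 called 6 transcripts for TCDD and 23 for trichloroethylene, and limma on log2(TPM + 1) called 0 and 8. When only the 5 libraries of the trichloroethylene comparison entered the fit, 450 transcripts passed. The transcript ENSRNOT00000001201 stood at 120 ± 15.4 TPM with TCDD and 124 ± 6.21 TPM with trichloroethylene (n = 3 each) beside 106 ± 0.108 TPM in controls. These are log2 changes of 0.03 ± 0.09 (SE; edgeR adjusted p = 0.95) and 0.1 ± 0.09 (adjusted p = 0.59), with 1 and 3 of 3 treated libraries above both controls. ENSRNOT00000004956 gave log2 changes of 0.02 ± 0.07 and -0.07 ± 0.07 (adjusted p = 0.97 and 0.64). Those of ENSRNOT00000065558 were larger, at 0.35 ± 0.14 and 0.4 ± 0.14 (adjusted p = 0.7 and 0.36), and those of ENSRNOT00000067423 were 0.15 ± 0.09 and 0.08 ± 0.09 (adjusted p = 0.71 and 0.7). For both of these transcripts, 3 of 3 libraries of each compound lay above both controls. The 2 compounds were also not told apart from each other at 6 h: edgeR called 0 transcripts (1432 at an unadjusted p under 0.05), limma 0 and DESeq2 5.

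**Figure D2:**
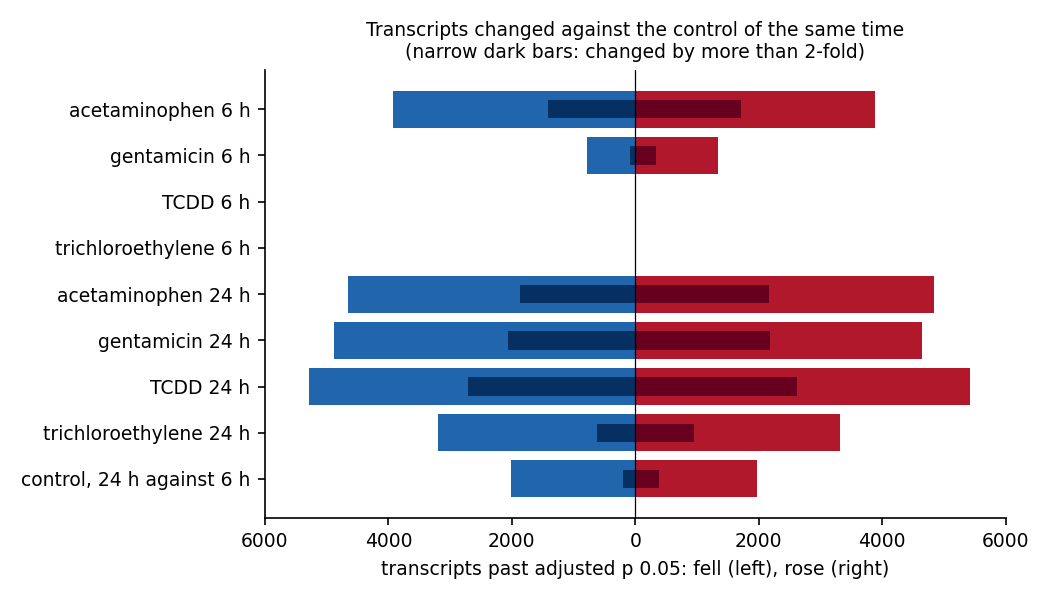
Number of transcripts past an edgeR adjusted p of 0.05 against the control of the same time, and in control between times (x axis, number of transcripts; red bars rose, blue bars fell, narrow dark bars changed by more than 2-fold). Counts run from 0 for TCDD and trichloroethylene at 6 h to 10701 for TCDD at 24 h.

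By 24 h, acetaminophen had changed 9500 transcripts against 3 controls, with 4838 that rose and 4662 that fell. More than 2-fold changes numbered 4026, of which 2161 were rises. ENSRNOT00000067423 was again far below control, at 6.18 ± 1.1 TPM beside 66.3 ± 5.83 TPM (SD, n = 3 each), a log2 change of -3.61 ± 0.09 (SE; edgeR adjusted p = 6.1e-20). ENSRNOT00000004956 fell from 1910 ± 98.7 to 316 ± 21.4 TPM, a log2 change of -2.77 ± 0.07 with the same adjusted p. Both lay below the controls in 3 of 3 libraries, as did ENSRNOT00000001201 at 67.3 ± 8.8 TPM (log2 change -0.79 ± 0.08, adjusted p = 6.3e-09). ENSRNOT00000065558, which had fallen at 6 h, rose from 2.23 ± 0.444 to 8.28 ± 1.41 TPM (log2 change 1.71 ± 0.12, adjusted p = 4.1e-12). Rises made up 50.9% of the calls, but 64.5% with total counts as the scale and 61.8% on log2(TPM + 1), so the balance of directions depends on the scaling.

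Gentamicin at 24 h changed 9525 transcripts (4646 rose, 4879 fell), and 930 of the rises exceeded 4-fold, against 418 of the falls. The 61 transcripts that appeared, with no count in any control library and at least 10 in every treated one, were the most numerous of any comparison; 17 disappeared by the same measure. ENSRNOT00000065558 rose from 2.23 ± 0.444 to 76.3 ± 10.4 TPM (SD, n = 3 each), a 37.5-fold rise with a log2 change of 5.23 ± 0.12 (SE; edgeR adjusted p = 1.2e-20). ENSRNOT00000001201 rose from 103 ± 6.35 to 1350 ± 74.4 TPM, a log2 change of 3.85 ± 0.09 with the same adjusted p. ENSRNOT00000004956 fell to 896 ± 118 TPM from 1910 ± 98.7 TPM in controls (log2 change -0.96 ± 0.06, adjusted p = 3.1e-12). All 3 treated libraries were beyond the controls for each of these transcripts. Rises were 48.8% of the calls, and 35.2% with total counts as the scale.

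TCDD changed 10701 transcripts at 24 h (5423 rose, 5278 fell), after giving no call at 6 h. With fragment length as a covariate, chosen after the data were seen, the count was 7729, below those of gentamicin (9427) and acetaminophen (8750) in the same fit. The median log2 change was 0.97 for rises and -1.03 for falls, and 5334 transcripts changed by more than 2-fold. ENSRNOT00000001201 rose to 1120 ± 273 TPM from 103 ± 6.35 TPM in controls (SD, n = 3 each), a log2 change of 3.8 ± 0.09 (SE; edgeR adjusted p = 3e-20). ENSRNOT00000004956 fell to 784 ± 144 TPM from 1910 ± 98.7 TPM (log2 change -0.93 ± 0.06, adjusted p = 5.3e-12). Every treated library lay beyond the controls for both. A small difference in ENSRNOT00000065558 (log2 change -0.37 ± 0.14, adjusted p = 0.02) did not pass without control replicate 1 (-0.34), control replicate 2 (-0.25), TCDD replicate 1 (-0.34) or TCDD replicate 2 (-0.3). With the fragment length covariate it was -0.1 (adjusted p = 0.924), and 2 of 3 treated libraries lay below the controls. Rises were 50.7% of the calls, but 31.8% on log2(TPM + 1), where the median of all transcripts shifted by -0.384. The TCDD libraries also had the lowest group mean of fragment length at 24 h, with 234 ± 3.91 bases between transcript length and effective length beside 278.5 ± 9.6 in controls.

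**Figure D3:**
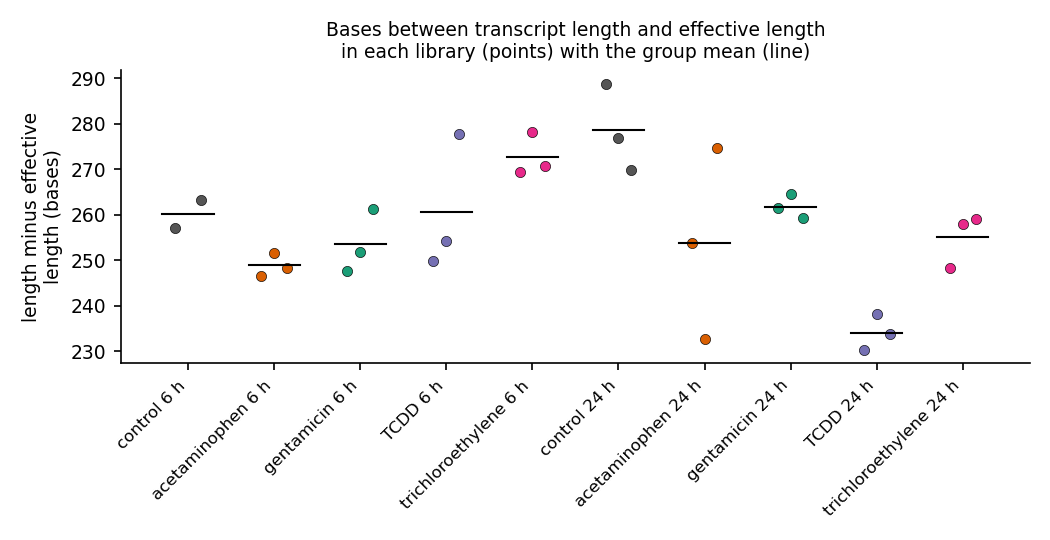
Bases between transcript length and effective length (y axis), a measure of the sequenced fragment length, in each of the 29 libraries (points) with the group mean (line), by treatment and time. TCDD at 24 h lies at 234 bases and control at 24 h at 278.5 bases.

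Trichloroethylene at 24 h changed 6505 transcripts (3315 rose, 3190 fell), the fewest of the 4 compounds at that time, and 1565 of them by more than 2-fold. The median log2 change was 0.69 among rises and -0.58 among falls. ENSRNOT00000004956 stood at 1220 ± 71.9 TPM beside 1910 ± 98.7 TPM in controls (SD, n = 3 each), a log2 change of -0.69 ± 0.06 (SE, edgeR adjusted p = 6.6e-09). At 6 h its means had been 1280 TPM with trichloroethylene and 1230 TPM in controls, so the gap at 24 h goes with the rise in control. ENSRNOT00000001201 fell to 74.5 ± 4.46 TPM from 103 ± 6.35 TPM (log2 change -0.51 ± 0.08, adjusted p = 1.5e-05), and ENSRNOT00000065558 rose from 2.23 ± 0.444 to 4.4 ± 0.153 TPM (log2 change 0.93 ± 0.12, adjusted p = 1e-06). In all of these cases 3 of 3 treated libraries were beyond the controls. For ENSRNOT00000067423 the log2 change was -0.06 ± 0.08 (adjusted p = 0.58), with 0 libraries beyond the controls. Rises were 51% of the calls, and 63.4% with total counts as the scale. With the fragment length covariate, 5248 transcripts passed.

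**Figure D4:**
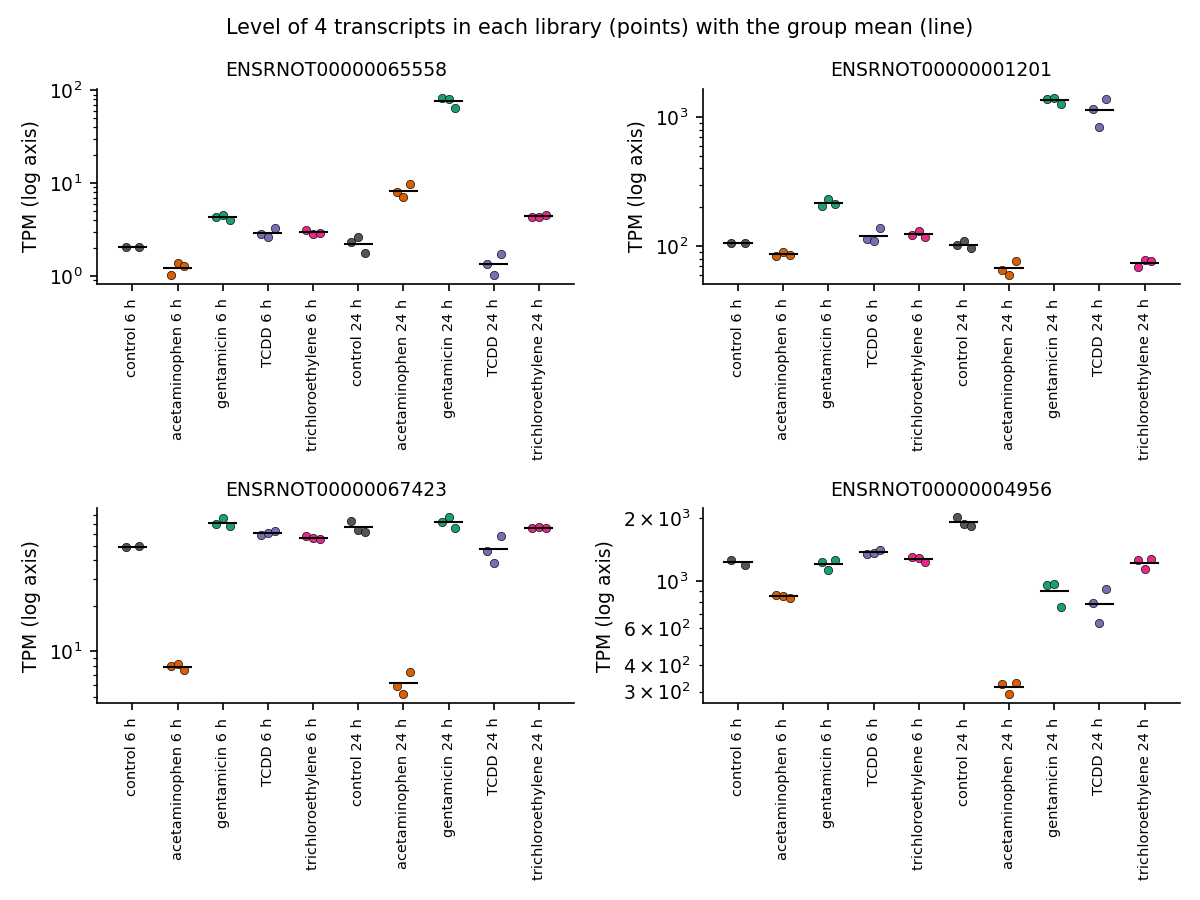
TPM (log axis) of 4 transcripts in each of the 29 libraries (points) with the group mean (line), by treatment and time. ENSRNOT00000001201 stands at 1350 TPM with gentamicin and 1120 TPM with TCDD at 24 h beside 103 TPM in controls, and ENSRNOT00000067423 is low only in the acetaminophen groups, at 7.93 and 6.18 TPM.

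Whether a compound's early changes lasted was asked by setting its 6 h calls beside its 24 h calls, which rest on separate controls. With acetaminophen, 2880 transcripts rose at both times and 2794 fell at both, where independent lists would share 1170 and 1140. These are 72.8% of the 6 h calls, while 368 transcripts changed in opposite directions. With gentamicin, 1019 rose at both times and 594 fell at both (387 and 238 for independent lists), or 76.3% of its 6 h calls, and 156 changed in opposite directions. A further 7756 transcripts passed for gentamicin at 24 h alone. Across transcripts, which are not independent replicates, the log2 changes at 6 h and 24 h correlated at r = 0.552 for acetaminophen, 0.307 for gentamicin, -0.052 for TCDD and -0.139 for trichloroethylene. Among transcripts changed more than 4-fold at 24 h, the 6 h change had the same sign in 1250 of 1343 for acetaminophen and 1103 of 1348 for gentamicin. For TCDD that held in 692 of 1615 and for trichloroethylene in 119 of 326.

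**Figure D5:**
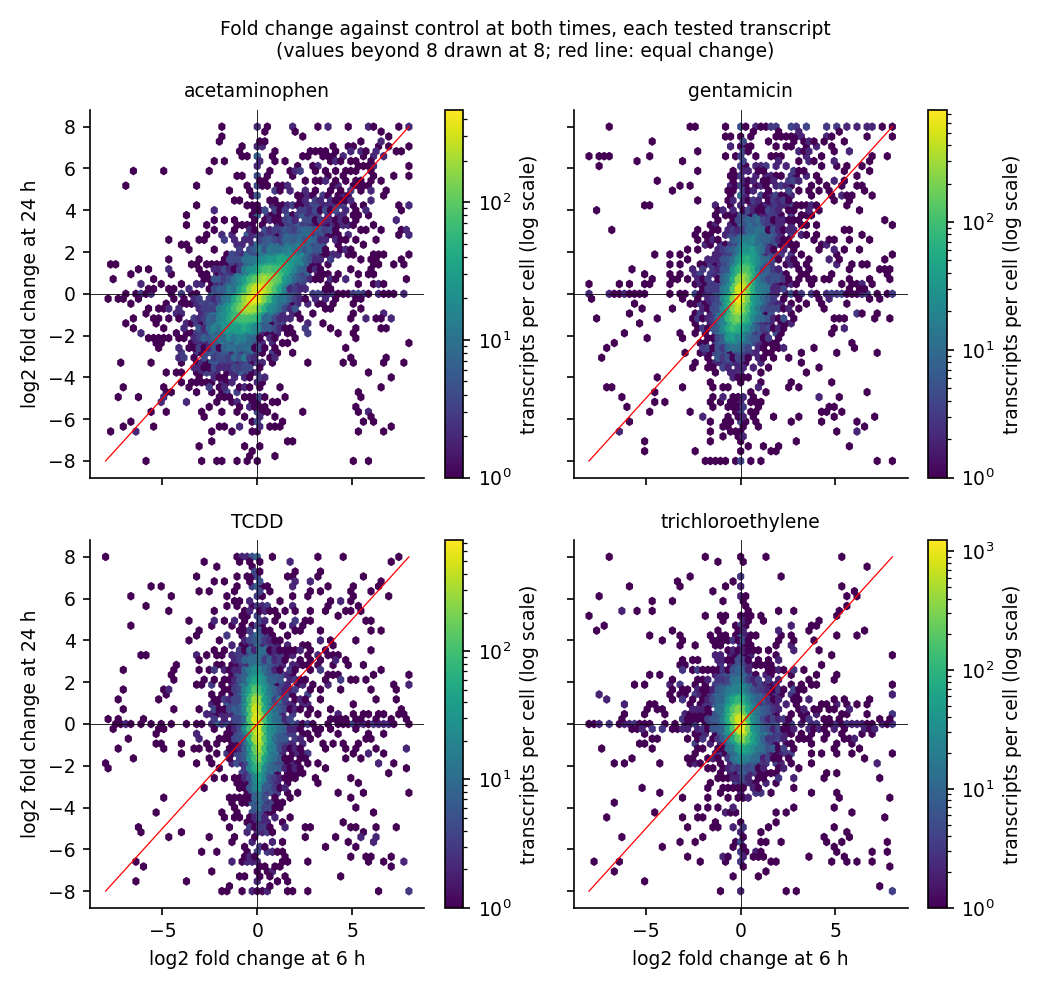
Log2 fold change against control at 6 h (x axis) and 24 h (y axis) for each tested transcript under each compound; colour gives the number of transcripts per cell on a log scale, and the red line marks equal change. The acetaminophen cloud follows the line (r = 0.552 across transcripts), while the TCDD cloud is upright (r = -0.052).

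The difference in effect between the times was itself tested. It passed for 4139 transcripts with acetaminophen, 6266 with gentamicin, 8959 with TCDD and 5282 with trichloroethylene. Of the acetaminophen transcripts called at 6 h, 2693 had a different effect at 24 h, and in 1812 of these the difference ran against the 6 h change. For gentamicin the same counts were 1287 and 361. These transcripts were picked by their 6 h call, and the 6 h effect is subtracted in the difference. The selection itself thus favours differences against the 6 h change. The share of positive differences depended on the scaling. For acetaminophen it was 48.3%, but 73.7% with total counts and 74.9% on log2(TPM + 1); for gentamicin 47.8%, 29.2% and 31.1%. For TCDD it was 48.5% and 25.4% on log2(TPM + 1), and for trichloroethylene 48.6% and 59.6% with total counts. With the fragment length of each library as a covariate, chosen after the data were seen, the trichloroethylene count was 2664.

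The compounds were next compared with each other at the same time. At 6 h, acetaminophen differed from TCDD in 8783 transcripts and from trichloroethylene in 9002, while gentamicin differed from them in 2571 and 2751. At 24 h the counts were 10709 between acetaminophen and gentamicin, 10979 between acetaminophen and TCDD, and 8842 between acetaminophen and trichloroethylene. Gentamicin and TCDD differed in 10903, gentamicin and trichloroethylene in 9869, and TCDD and trichloroethylene in 9480. Transcripts that passed against control and against each other compound in the same direction numbered 5880 for acetaminophen and 714 for gentamicin at 6 h. At 24 h they numbered 3487 for acetaminophen, 3881 for gentamicin, 4343 for TCDD and 658 for trichloroethylene. The gentamicin set at 24 h held 604 rises and 160 falls of more than 4-fold, and the TCDD set held 358 rises and 506 falls of that size.

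Responses also overlapped. At 24 h, 14461 transcripts (90.4% of those tested) changed with at least 1 compound, and 4655 of them rose with some compounds and fell with others. A set of 788 transcripts rose with all 4 compounds and 753 fell with all 4, where independent lists would share 98.8 and 93.7. Mean fragment length was lower than in controls with all 4 compounds at 24 h, though the acetaminophen libraries (232.7 to 274.7 bases) overlapped the controls (269.9 to 288.8). With fragment length as a covariate, chosen after the data were seen, the counts were 574 and 552 (independent lists 49.5 and 52.8). TCDD and trichloroethylene had the fewest opposite changes, with 4532 transcripts changed in the same direction and 705 in opposite directions (independent lists 2177 and 2176). For acetaminophen and gentamicin the counts were 4162 and 2140 (2828 and 2831), for acetaminophen and TCDD 4855 and 2117 (3180 and 3178), and for acetaminophen and trichloroethylene 3708 and 978 (1933 and 1932). Gentamicin shared 4903 with TCDD and 2086 ran opposite (3186 and 3188), and it shared 3002 with trichloroethylene and 1451 ran opposite (1937 and 1938). At 6 h acetaminophen and gentamicin shared 973, with 442 opposite (514 and 516). Simulated unchanged groups set against shared simulated controls had 0 calls in common in these pairs. Such groups give almost no calls to share, so this value says nothing of the overlap between lists of real changes. The 2 or 3 controls per time were not split between the compounds, since a part would hold a single library, so part of the excess may come from the shared controls. At 24 h the log2 changes of TCDD and trichloroethylene correlated across transcripts at r = 0.55. Simulated unchanged groups with shared simulated controls gave 0.49. The changes of acetaminophen and trichloroethylene correlated at 0.49 beside a simulated 0.49. The other pairs lay below the simulated correlation: acetaminophen and gentamicin at 0.39 beside 0.49, acetaminophen and TCDD at 0.43 beside 0.5, gentamicin and TCDD at 0.45 beside 0.49, and gentamicin and trichloroethylene at 0.4 beside 0.5. The simulated groups held no effects, and effects particular to a compound lower a correlation, so these comparisons cannot decide on shared effects. The covariance, to which shared controls add the same amount with or without real effects, lay above its simulated value in all 6 pairs. It ran from 0.629 for gentamicin and trichloroethylene (simulated 0.144) to 1.1 for gentamicin and TCDD (simulated 0.142), with 0.888 for TCDD and trichloroethylene (simulated 0.139). The simulated values were taken over the transcripts kept in each simulated fit, 14946 on average, and the real ones over 15990. At 6 h, TCDD and trichloroethylene also exceeded the simulated value (0.487 beside 0.212) without an edgeR call. An excess over this baseline therefore does not by itself show shared effects.

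Without any compound, 3985 transcripts differed between 24 h and 6 h in culture (1973 rose, 2012 fell), and 587 of them by more than 2-fold. ENSRNOT00000004956 rose from 1230 ± 49.1 TPM (SD, n = 2) to 1910 ± 98.7 TPM (n = 3), a log2 change of 0.48 ± 0.07 (SE; edgeR adjusted p = 7.2e-05), with 3 of 3 later libraries above the earlier ones. ENSRNOT00000065558 and ENSRNOT00000001201 gave log2 changes of -0.03 ± 0.14 (adjusted p = 0.91) and -0.19 ± 0.09 (adjusted p = 0.12). With fragment length as a covariate, chosen after the data were seen, the latter passed (-0.27, adjusted p = 0.0445). ENSRNOT00000067423 passed at 0.28 ± 0.09 (adjusted p = 0.019), but not with that covariate (0.22) or without control 6 h replicate 2 (0.27), control 6 h replicate 3 (0.29) or control 24 h replicate 1 (0.22). Rises were 49.5% of the calls, and 69.1% on log2(TPM + 1). The count was 1633 without control 6 h replicate 2, 1804 without control 6 h replicate 3 and 2116 without control 24 h replicate 1, and 2262 with fragment length as a covariate.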

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

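The splits of the libraries, the slopes between the times, the comparison of control with TCDD libraries at 6 h and the counts and shares by class of transcript length were tests chosen after the results were seen; the fragment length covariate was added after the data were seen, with its bound set before its value was known.

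The effect of every compound differed between 6 h and 24 h by an interaction test. The counts were 4139 transcripts for acetaminophen, 6266 for gentamicin, 8959 for TCDD and 5282 for trichloroethylene. Of the named transcripts, ENSRNOT00000065558 had a 24 h effect that exceeded its 6 h effect by a log2 value of 2.4 with acetaminophen, 4.28 with gentamicin and 0.54 with trichloroethylene, and by -0.71 with TCDD. For ENSRNOT00000001201 the differences were 2.94 with gentamicin, 3.77 with TCDD, -0.55 with acetaminophen and -0.62 with trichloroethylene. For ENSRNOT00000067423 they were -1.02 with acetaminophen and -0.28 with TCDD, the latter close to the threshold (edgeR adjusted p = 0.042). For ENSRNOT00000004956 they were -2.29 with acetaminophen, -0.81 with gentamicin, -0.94 with TCDD and -0.62 with trichloroethylene. Its level in control rose between the times by a log2 value of 0.48, which enters each of these differences. For ENSRNOT00000065558, the TCDD effects were 0.35 at 6 h and -0.37 at 24 h. They lay closer together with the fragment length covariate, at 0.34 and -0.1.

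TCDD and trichloroethylene changed 10701 and 6505 transcripts at 24 h, and edgeR called none at 6 h. A response of the full 24 h size would give a slope of the 6 h on the 24 h log2 change near 1. It could hardly have stayed hidden, since the median SE was 0.174 at 6 h, close to 0.159 (TCDD) and 0.155 (trichloroethylene) at 24 h. The slope over the transcripts called at 24 h was -0.02 for TCDD (-0.04 to 0 with each library left out) and -0.09 for trichloroethylene (-0.12 to -0.07). It was 0.59 for acetaminophen and 0.23 for gentamicin. A weaker hidden response would give a smaller slope. The changes of TCDD and trichloroethylene rose with transcript length at 6 h (Spearman rho = 0.31 and 0.29) and fell with it at 24 h (-0.2 and -0.09), which lowers the slope. The slope thus cannot decide on a weaker response. An exchange of libraries between control and TCDD at 6 h cannot be told apart from similar samples: the correlation between the controls exceeded the highest correlation of a control with a TCDD library by 0.0036. Other early changes stay open, since DESeq2 called 6 transcripts for TCDD and 23 for trichloroethylene and a fit of only the groups compared called 450 for trichloroethylene (146 rose, 304 fell), so a main response after 6 h may explain the pattern only as an untested hypothesis.

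The TCDD response at 24 h came with a lower mean fragment length than in controls (-44.5 bases), as did those to acetaminophen (-24.8), trichloroethylene (-23.4) and gentamicin (-16.8). With fragment length as a covariate, the median ratio of adjusted to unadjusted log2 changes over the called transcripts was 0.83 (0.82 to 0.86 with each library left out). The covariate's effect came from differences within groups and was assumed the same between groups. TCDD libraries (230.3 to 238.1 bases) and controls (269.9 to 288.8) did not overlap at 24 h. The ratio thus cannot decide whether fragment length was the whole cause. The count fell to 7729, while the median SE rose from 0.159 to 0.235. The log2 change fell with transcript length (Spearman rho = -0.2 across transcripts, -0.23 to -0.15 with each library left out). This was too close to 0.2, the bound of a first test, to decide. In each of 4 equal classes of transcript length, a later test found at least 302 transcripts changed by more than 2-fold in either direction. Strict length bias would move transcripts of similar length in the same direction. The directions were uneven, with 1528 rises and 949 falls called in the shortest class and 723 and 2015 in the longest. The test was chosen after rho was known, so it cannot decide. Length bias and fragment length stay open as causes beside the compound itself.

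The controls differed between 24 h and 6 h in 3985 transcripts, while their fragment length measure was higher by 18.3 bases at 24 h. With that measure as a covariate the median ratio of log2 changes was 0.79 (0.75 to 0.84 with each library left out), and 2262 transcripts passed. The median SE moved only from 0.174 to 0.177, so the lower count goes with smaller changes. The controls did not overlap in fragment length between 6 h (257.1 to 263.2 bases) and 24 h (269.9 to 288.8). The covariate's effect came from differences within groups, so the ratio cannot decide whether fragment length was the whole cause. Both measures used for TCDD lean towards length bias here: rho was 0.26 (0.22 to 0.29 with each library left out), beyond 0.2, and the longest of 4 equal classes held only 12 falls over 2-fold, so for changes of that size, too few to decide, length bias cannot be told apart. Over all sizes, the less frequent direction held at least 0.2 of the calls in each class (0.156 to 0.25 with each library left out). The shortest class held 218 rises and 694 falls, and the longest 875 and 219. This share was chosen after these counts were known, so it cannot decide either. Length bias and fragment length stay open as causes beside time in culture.

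With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. Every split but the real one mixes libraries of both groups on each side, which shrinks the difference and raises the spread. Low counts there follow from the design where the groups differ, so they decide nothing. Against control at 24 h, 1 of the 10 splits, the real one, gave as many calls for each compound. The real and the highest other count were 9500 and 9 for acetaminophen, 9525 and 0 for gentamicin, 10701 and 1 for TCDD, and 6505 and 0 for trichloroethylene. Between compounds at 6 h, the highest other count was 0 for acetaminophen against gentamicin (real 8711), TCDD (8783) and trichloroethylene (9002), and for gentamicin against TCDD (2571) and trichloroethylene (2751). TCDD against trichloroethylene at 6 h gave a real count of 0, a highest other of 1, and 10 of 10 splits with as many. At 24 h the pairs gave 10709 and 1 for acetaminophen and gentamicin, 10979 and 2 for acetaminophen and TCDD, 8842 and 1 for acetaminophen and trichloroethylene, 10903 and 129 for gentamicin and TCDD, 9869 and 0 for gentamicin and trichloroethylene, and 9480 and 7 for TCDD and trichloroethylene.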

How the results depend on the processing

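The effective length offset, the fragment length covariate and the total count scale were chosen after the data were seen. The 4 counts at 24 h stayed within 1.5 times under all 11 alternatives and with each library left out: 8055 to 9643 and 8771 to 9176 for acetaminophen, 7999 to 9996 and 8873 to 9053 for gentamicin, 7729 to 10771 and 9939 to 10397 for TCDD, 5248 to 6809 and 5387 to 6348 for trichloroethylene. A like count need not hold the same transcripts. With the fragment length covariate, 7014 of the 10701 TCDD calls and 4441 of the 6505 trichloroethylene calls passed again. For acetaminophen these were 7883 of 9500, and for gentamicin 8640 of 9525. On log2(TPM + 1), 8622 of the TCDD calls passed again among 10571. At 6 h, acetaminophen gave 6265 to 7229 with a library left out. Gentamicin gave 881 to 1687, lowest without control replicate 2; TCDD 0 to 3 and trichloroethylene 0 to 2, both highest without control replicate 3. The control time comparison gave 1633 to 4304. Leaving out a control at 6 h leaves 1 library, assumed to vary like the other groups.

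Where edgeR called 0 at 6 h, DESeq2 called 6 for TCDD and 23 for trichloroethylene, limma on log2(TPM + 1) called 8 for trichloroethylene, and a fit of only the groups compared called 450; the cause was not tested. With the fragment length covariate, the trichloroethylene time interaction fell from 5282 to 2664 and the control time comparison from 3985 to 2262. In the first, the median ratio of log2 changes was 0.74 and the median SE rose from 0.235 to 0.261.

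Deviations of same-numbered libraries correlated between -0.193 and 0.0838 for treated and control, and between -0.212 and 0.32 over all 45 pairs of groups (other numbers -0.292 to 0.199). In 0 of the 36 pairs with 3 shared numbers did all 3 exceed 0.1. The replicate block gave 7631 and 1964 calls for acetaminophen and gentamicin at 6 h and changed no count by over 1.5 times. For the 4 named transcripts, 376 values were computed under other settings: no called change reversed, 16 lost the call and 3 gained it. Some changes that had not passed took the opposite sign, such as ENSRNOT00000067423 with TCDD at 24 h, at -0.12 and at 0.02 with the fragment length covariate.

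Against TMM, total counts shifted the median log2 change at 24 h by 0.21 for acetaminophen and -0.228 for gentamicin, and the time interactions by 0.219, -0.241 and, for TCDD, -0.107. The TPM scale shifted it by 0.108, 0.128 and 0.121 at 6 h for gentamicin, TCDD and trichloroethylene, by 0.15, -0.141 and -0.384 at 24 h for acetaminophen, gentamicin and TCDD, by 0.208, -0.248 and -0.51 for their interactions, and by 0.141 for control time. Gene list tests were not run, and transcripts in place of gene sums is the analysis reported. In simulated acetaminophen libraries at 6 h, 35% of 1.5-fold changes were recovered. Only 200 of 14946 transcripts were changed there, which makes the adjusted p stricter than in the real comparison, where 48.8% passed. The 35% is thus not the share found in the real data, and depth was not varied.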

Other observations

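Some transcripts behaved like switches. Counting called transcripts with no count in any library of 1 group and at least 10 in every library of the other, 32 appeared and 9 disappeared with acetaminophen at 24 h, 31 and 22 with TCDD, and 3 and 4 with trichloroethylene. At 6 h the counts were 6 and 3 with gentamicin, and in control 3 appeared and 6 disappeared between 6 h and 24 h. The median level of the appearing transcripts was 3.1 TPM with gentamicin at 24 h (61 transcripts) and 1.85 TPM with TCDD.

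The number of detected transcripts was recorded for each library. Transcripts with at least 5 counts numbered 14761 ± 102 in control at 6 h (SD, n = 2) and 14887 ± 52.4 at 24 h (n = 3), and 15334 ± 74.5 with acetaminophen, 15112 ± 153 with gentamicin, 15085 ± 165 with TCDD and 15135 ± 75.5 with trichloroethylene at 24 h (n = 3 each); these differences were not tested. The 10 most abundant transcripts held 4.96 ± 0.181% of counts with acetaminophen at 24 h, beside 6.48 ± 0.223% in control.

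Although TCDD and trichloroethylene gave no edgeR call at 6 h, their log2 changes had a covariance of 0.487 across transcripts. Simulated unchanged groups that share 2 simulated controls gave 0.212. The correlation of TCDD and trichloroethylene was 0.63 beside a simulated 0.6. By covariance the pair does not stand apart. Each other pair at 6 h also exceeded its simulated value, from 0.379 (acetaminophen and trichloroethylene, simulated 0.209) to 0.495 (acetaminophen and gentamicin, simulated 0.208). The simulated covariances were taken over fewer transcripts than the real ones. By correlation, TCDD and trichloroethylene were the only pair at 6 h above the simulated value. The simulated groups held no effects, and effects particular to a compound lower a correlation. Pairs with many calls therefore tend to lie below the simulated value, so this order does not show a shared effect. The spread between the simulated draws is not given. The others ran from 0.32 (acetaminophen and trichloroethylene, simulated 0.6) to 0.51 (gentamicin and TCDD, simulated 0.6). The changes of TCDD and trichloroethylene also rose with transcript length, at Spearman rho = 0.31 and 0.29 across transcripts. Within groups, 3619 of the tested transcripts followed the fragment length of the libraries.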
